A study of Mus musculus with 6 samples.

How the data were processed

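Ly6Chi monocytes were sorted by flow cytometry from blood or from the small intestine lamina propria (SILP) of infected C57BL/6NTac mice on day 8, and total RNA was measured on Illumina bead arrays, 3 per tissue. Per the labels, RNA was extracted with Trizol, biotinylated cRNA was made with a MessageAmp kit, and each tissue had 3 biological replicates from pooled animals. Samples were grouped by the tissue in their labels, and the only comparison was SILP against blood. The deposited table of non-normalized values gives an intensity per probe on a linear scale, with no normalization between arrays visible in the values. The detection p-value beside each signal in the deposited table moves in steps of 1 over 936, as a rank among that many negative control probes would. The scanner software, its version and its background setting were not given in the sources used here. A value table deposited by the authors holds intensities of the same arrays on 2 scales. Its SILP columns hold 1 set of sorted values, with a median of 116.88 and a largest difference of 0.32 between sorted columns, as quantile normalization gives. That set differs by up to 7.04% from the mean of the 3 sorted SILP arrays and by up to 14.5% from that of all 6 arrays. The blood columns equal the non-normalized signals (medians 118.531, 109.501 and 109.806). The step by which the SILP columns were made is unknown, so that table served only as an alternative.

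Each array held 45281 probes. The annotation table gave 1 gene symbol for 34885 probes and several for 18, and 10378 probes were not listed in it and stayed unnamed. Of the probes, 34807 had a gene identifier found in the RefSeq table, and no symbol changed through it. Probes detected at a detection p under 0.01 numbered 14912, 14957 and 13887 on SILP replicates 1 to 3 and 14780, 15931 and 14396 on blood replicates 1 to 3. The number of arrays limits the precision, and SILP replicate 3 had a lower ratio of detected to undetected signal (1.83) than any other array (2.67 to 3.10).

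Signals were corrected for background with limma's neqc, which took the background from the detection p-values, added an offset of 16 and quantile normalized all 6 arrays, and log2 values were used. An offset shrinks the differences of dim probes, and quantile normalization gives every array the same distribution. The 14405 probes detected on all 3 arrays of at least 1 tissue were tested with limma (lmFit and eBayes) by tissue alone, with Benjamini-Hochberg adjustment, and a probe was called at an adjusted p under 0.05. Adjusted p-values in the text come from limma unless a list test is named. A gene was represented by the kept probe with the highest mean over the 6 arrays, which left 7976 genes, of which 2880 had several kept probes. Among the 40 called genes with several kept probes, all were called the same way in 31, another probe was not called in 9, and none was called the other way. Where a probe was undetected on all arrays of a tissue, its fold is given as a lower bound. The bound set the mean log2 value of the brighter tissue against the mean, in the dimmer tissue, of the higher of the lowest signal of any detected probe on each array and the probe's own value.

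The comparison, the test, the filters, 23 gene lists, 16 lists of cell type markers and most alternatives were fixed before the data were examined. Of 963 list members, 870 matched a symbol on the array. Lists with at least 5 kept genes, 32 in all, were tested with limma's camera with a preset correlation between genes of 0.01, adjusted over the lists, with an estimated correlation and fry as alternatives; fry tests whether a list's genes move one way on balance and compares them with no other genes. A list of pancreatic acinar genes was added after the data were seen and was not tested. Genes were named by a rule fixed in advance: the 10 highest and 10 lowest log2 differences among called genes with no overlap between tissues, leaving out predicted genes, then 22 genes whatever their result, then up to 4 called members of each gene list and up to 3 measured members of each marker list. Of the 22 genes, 19 had a probe. Hspa8, Hsp90aa1, Cxcl9, Cxcl10, Ccl2 and other genes outside the rule were chosen after their values were seen.

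Alternatives covered the deposited value table, other background corrections and normalizations, the offset, the filter on dim probes, the replicate number as a block, the intensity trend, array weights, 1 probe per gene and leaving out each array. Leaving out an array repeated the normalization. Settings that filtered dim probes again without SILP replicate 3, tested named probes only, or ran the other list tests without SILP replicate 3 were chosen after seeing the data. The design allows 10 splits of the 6 arrays into groups of 3, so an exact permutation p could not go below 0.1.

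The procedure was tested on simulated data for this comparison, with 200 probes changed by a log2 difference of 1, 2 or 3 either way. The simulation passed the filter with 18188 probes, more than the real data. Of probes changed by 1, 0 of 34 raised and 0 of 33 lowered were called. Of those changed by 2, 13 of 34 and 13 of 33 were called, and of those changed by 3, 19 of 33 and 20 of 33. No changed probe was called the wrong way, and 2 unchanged probes were called. Of 34 lists the 1 that was shifted was called and 0 others. Noise was drawn independently for each probe, so the simulation could not show how correlation between genes affects the list calls. Computations used R 4.3.3 with limma 3.58.1 and statmod 1.5.0, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.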

Results

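Gene expression was measured in Ly6Chi monocytes, the inflammatory monocytes that leave the bone marrow for infected tissue, sorted from C57BL/6NTac mice on day 8 of infection with the intracellular parasite Toxoplasma gondii. The cells came either from blood or from the small intestine lamina propria, the connective tissue under the gut epithelium, abbreviated SILP. Each tissue was represented by 3 arrays, which the labels describe as biological replicates from pooled animals. Each array held 45281 probes, of which 13887 to 15931 were detected per array, and the number of arrays limits the precision. The median signal of detected probes over that of undetected probes was 3.10 and 3.08 on SILP replicates 1 and 2, 1.83 on SILP replicate 3, and 3.05, 2.67 and 2.89 on the blood arrays. The single comparison that the labels imply, SILP against blood, asks how gene expression in these monocytes differed with the tissue they were taken from.

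Transcripts of chemokines and of interleukins with opposed actions were higher in the sorted monocyte samples from the SILP than in those from blood. Measured markers of T cells, epithelium and stroma were higher on the same SILP arrays (median log2 difference 2.20, 2.94 and 2.51). These medians cover the 8, 7 and 8 genes kept by the filter, of 14, 25 and 22 with a probe. Cxcl2, a chemokine that attracts neutrophils, was at least 132-fold higher in the SILP (12.52 ± 0.55 log2, SD, n = 3, and not detected on any blood array, adjusted p = 4.06e-04). Il1b, which encodes the inflammatory cytokine interleukin-1 beta, was 44.1-fold higher (log2 difference 5.46 ± 0.63 SE, n = 3 arrays per tissue, adjusted p = 0.00659). It was 27.6-fold without blood replicate 2 and 67.6-fold without blood replicate 3. Il10, which encodes an anti-inflammatory cytokine, was at least 12.8-fold higher (adjusted p = 4.06e-04). Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis, was 21.8-fold higher (log2 difference 4.45 ± 0.53 SE, adjusted p = 0.00750), and 14.5-fold without blood replicate 2. By contrast Ly6c1, a gene of the surface antigen used to define the population, differed by -0.35 (log2, adjusted p = 0.494), from 10.90 ± 0.21 (SD, n = 3) in the SILP to 11.25 ± 0.17 in blood. In all, 376 of 14405 probes were higher and 62 lower in the SILP at an adjusted p under 0.05 from limma, each with a fitted difference of at least 2-fold. These stood for 170 genes higher and 24 lower out of 7976. Of the probes called higher, 252 were not detected on any blood array, and for their genes only a lower bound of the fold is given, which can lie under 2-fold. The 3 SILP values did not overlap the 3 blood values at 4032 probes (28.0%), against 10% by chance.

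**Figure D1:**
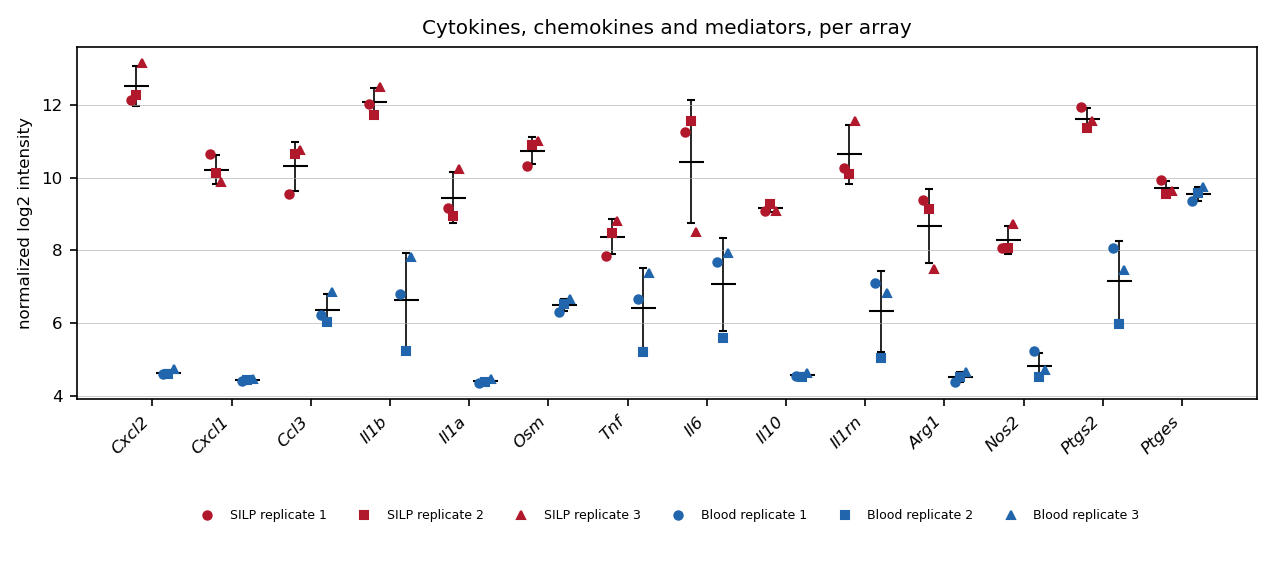
Normalized log2 intensity of 14 genes of cytokines, chemokines and mediators (vertical axis) on the 3 SILP arrays (red) and the 3 blood arrays (blue), with bars for the mean and SD. The SILP values of Cxcl2, Cxcl1, Il1a, Il10 and Arg1 lay above all blood values, and those of Ptges overlapped them.

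Of 18 chemokine genes measured, 11 rose, none fell and 7 did not pass the test (median log2 difference 2.83, or 2.25 with undetected genes at their bound, adjusted p = 9.64e-20, and adjusted p = 0.0633 with an estimated correlation). Adjusted over the list alone, 14 rose. The risen members included the neutrophil attractants Cxcl2, Cxcl1 (at least 26.9-fold) and Cxcl3 (at least 14.0-fold), the monocyte attractant Ccl2 (14.0-fold) and Ccl3 (15.4-fold). The bound for Cxcl3 was 21.4-fold without SILP replicate 1 and 6.86-fold without SILP replicate 3, and Ccl2 was 8.75-fold without SILP replicate 2 and 22.2-fold without SILP replicate 3. The other risen members were Ccl4, Ccl8, Ccl11, Ccl24, Cxcl12 and Cxcl13. Without SILP replicate 1 the bounds for Cxcl12 and Cxcl13 were 2.86-fold and 2.34-fold, and without SILP replicate 2 they were 5.86-fold and 4.02-fold. The bound for Ccl24 went the other way, at 4.07-fold without SILP replicate 1 and 2.29-fold without SILP replicate 2. Cxcl9 and Cxcl10, chemokines induced by interferon-gamma, differed by 0.07 and 1.04 (log2). Neither passed the test. Of members with a probe, 18 of 23 chemokine and 17 of 26 inflammatory cytokine genes were kept by the filter. It kept 23 of 34 macrophage maturation and 17 of 31 matrix remodelling genes. Genes undetected in blood were kept only where every SILP array detected them, which favours high medians in these lists too. Of 17 inflammatory cytokine genes, 7 rose and none fell (median 2.10, or 1.80 with undetected genes at their bound, adjusted p = 9.14e-15, and adjusted p = 0.0633 with an estimated correlation). Adjusted over the list alone, 9 rose. They included Il1a, the second interleukin-1 gene (at least 15.8-fold), Osm, which encodes oncostatin M (19.0-fold), and Vegfa, an angiogenic growth factor (21.0-fold, or 32.3-fold without blood replicate 2). Tnf had a log2 difference of 1.97 ± 0.57 (SE) and an adjusted p of 0.156. Il6 had a log2 difference of 3.38 ± 0.95 (SE) with an adjusted p of 0.148, and of 4.29 with 0.0187 when SILP replicate 3 was left out, and over all alternative settings its adjusted p ran from 0.00134 to 0.420. On that array neutrophil markers had a median 3.10 above the other SILP arrays on the log2 scale. Without it the chemokine and cytokine medians were 3.08 and 1.78.

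Of 24 regulatory cytokine and checkpoint genes, 8 rose, none fell and 16 did not pass the test (median 0.96, adjusted p = 9.14e-15, and adjusted p = 0.0648 with an estimated correlation). Adjusted over the list alone, 12 rose. Il10 stood at 9.15 ± 0.11 (log2, SD, n = 3) in the SILP and was not detected on any blood array. Il1rn, which encodes the interleukin-1 receptor antagonist, was 19.9-fold higher (adjusted p = 0.0154), and 12.9-fold without blood replicate 2. Arg1, arginase 1, was at least 9.15-fold higher (14.0-fold without SILP replicate 3) and Arg2 15.9-fold higher (9.52-fold without SILP replicate 3). Ido1, a tryptophan-degrading enzyme, and the checkpoint ligand Pdcd1lg2 were at least 7.71-fold and at least 2.44-fold higher. In the list on reactive oxygen, arginine and nitric oxide metabolism, Arg1, Arg2 and Nos2 (at least 7.02-fold), the inducible nitric oxide synthase, were the 3 risen genes of 12 (median 0.62, adjusted p = 9.38e-06, and adjusted p = 0.0648 with an estimated correlation). Of 12 genes of the prostaglandin and leukotriene pathway, Ptgs2, at 11.61 ± 0.29 in the SILP and 7.16 ± 1.09 in blood, was the only member called. Ptges, the prostaglandin E synthase downstream of it, stood at 9.71 ± 0.21 in the SILP and 9.55 ± 0.20 in blood (log2, SD, n = 3, adjusted p = 0.742). The pathway list as a whole was not called (median -0.12, mean 0.14, tested direction up, adjusted p = 0.395), and its median was -0.26 without SILP replicate 2 and 0.10 without SILP replicate 3. When arginine and nitric oxide and prostaglandin pathway genes were each adjusted over the list alone, 3 and 1 rose and 0 and 0 fell, in that order. On the same SILP arrays T cell, epithelial and stromal markers had medians of 2.20, 2.94 and 2.51 above blood.

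Immediate early and stress genes respond within minutes to stimulation. Of 32 such genes measured, 14 rose and none fell (median 1.65, adjusted p = 6.42e-21, and adjusted p = 0.0671 with an estimated correlation). Adjusted over the list alone, 21 rose. Fosb (30.3-fold), Egr3 (at least 15.2-fold), Dusp5 (19.8-fold) and Ppp1r15a (20.2-fold) were among them, while the heat shock genes Hspa8 and Hsp90aa1 differed by -0.30 and 0.06 (log2, not called). Fosb was 46.4-fold without blood replicate 1 and 19.9-fold without blood replicate 2, and the bound for Egr3 was 8.02-fold without SILP replicate 3. Of 25 targets of the transcription factor NF-kB, 3 rose, namely Ier3, Rel and Nfkbiz (median 1.32, adjusted p = 1.09e-15, and adjusted p = 0.178 with an estimated correlation). Adjusted over the list alone, 15 rose. Nfkbiz lost its call when any array other than SILP replicate 3 was left out (adjusted p = 0.0563 to 0.103 in limma). Rel lost its call when any single blood array was left out (adjusted p = 0.0670 to 0.0912 in limma). Of 32 genes of Toll-like and NOD-like receptor signalling, Cd14, the endotoxin co-receptor, rose 24.5-fold and no other was called (median 0.46, adjusted p = 1.90e-04, and adjusted p = 0.178 with an estimated correlation). Of 29 type I interferon stimulated genes, only Rsad2, an antiviral enzyme, was called (12.2-fold), and the median was 0.86 (adjusted p = 7.97e-12, and adjusted p = 0.204 with an estimated correlation). Of 29 interferon-gamma inducible genes, which include the GTPases that attack the parasite's vacuole, Nos2 and Ubd rose (median 0.20, adjusted p = 0.00493, and adjusted p = 0.503 with an estimated correlation). The list's call was lost without SILP replicate 3 (adjusted p = 0.507). The interferon-gamma list's median was -0.02 without SILP replicate 3 and 0.01 without blood replicate 2, that of the type I interferon list 0.53 without SILP replicate 3 and that of the Toll-like receptor list 0.27 without SILP replicate 3. Ifng itself, a cytokine of T and NK cells, was at least 12.8-fold higher in the SILP, beside the T cell markers Cd3g and Cd3e. In the unfolded protein response list none of 22 genes was called (median -0.24, adjusted p = 0.936). The unfolded protein median was -0.39 without SILP replicate 1 and 0.06 without SILP replicate 3. When Toll-like receptor, type I interferon, interferon-gamma and unfolded protein response genes were each adjusted over the list alone, 1, 5, 2 and 0 rose and 0, 0, 0 and 0 fell, in that order.

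**Figure D2:**
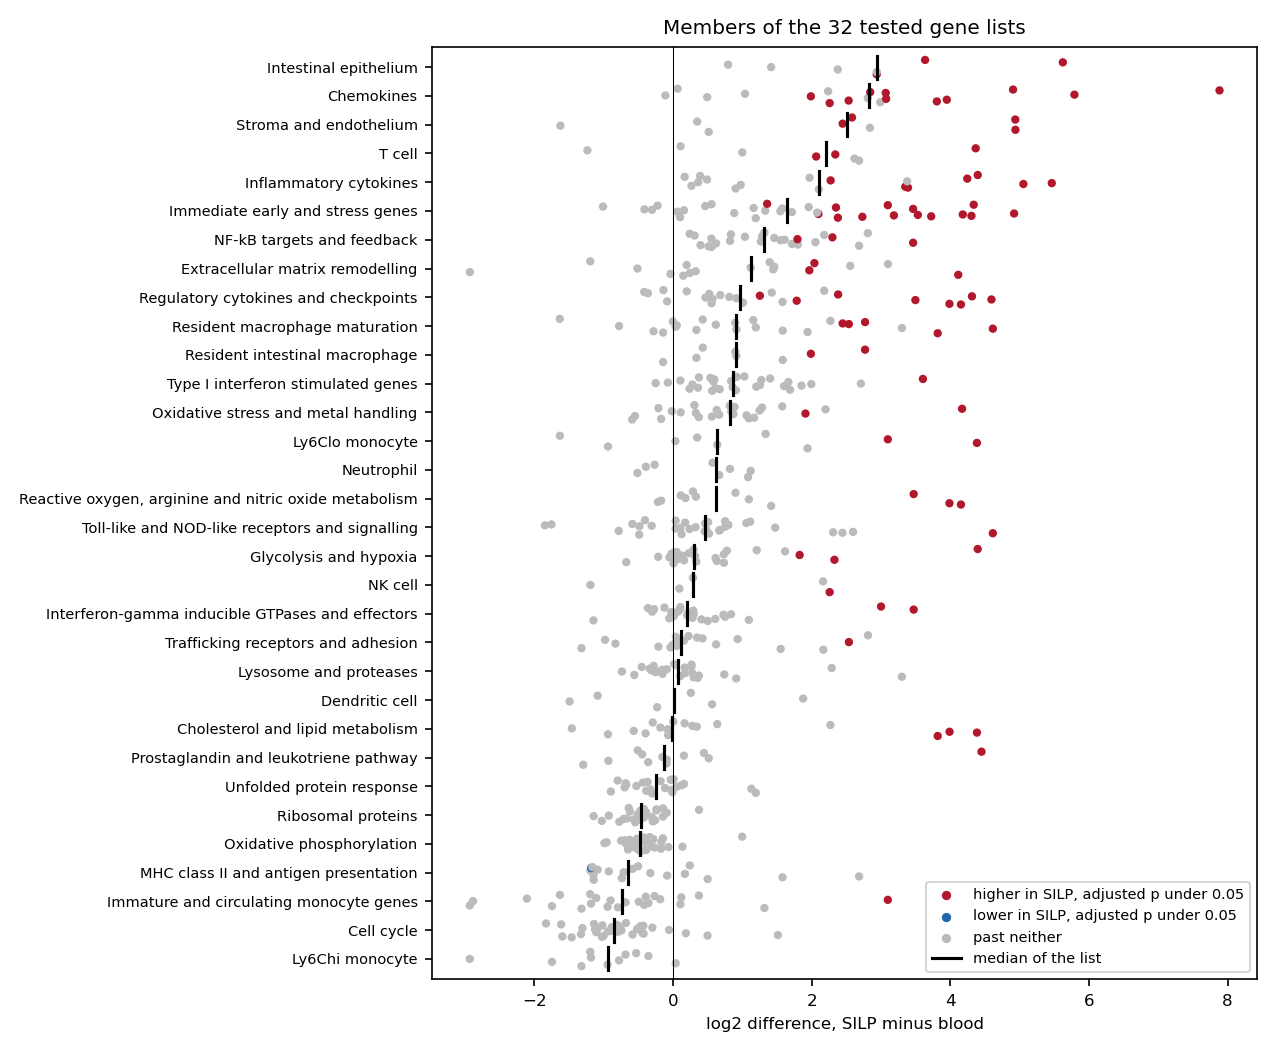
Log2 difference between SILP and blood (horizontal axis) of each measured member of the 32 tested gene lists, with genes past the test in colour and a bar at each list's median. Chemokines had a median of 2.83 and the Ly6Chi monocyte markers one of -0.94.

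Few genes of monocyte identity were called. Csf1r, the macrophage growth factor receptor, and Adgre1, a receptor used as a macrophage marker, differed by 0.04 and -0.14 (log2, adjusted p = 0.970 and 0.903), and the sign of each changed between settings. Ccr2, the receptor for leaving the bone marrow, stood at 8.73 ± 1.63 in the SILP and 10.05 ± 0.16 in blood (log2, SD, n = 3, adjusted p = 0.449), with 6.85 on SILP replicate 3. None of 11 markers of Ly6Chi monocytes was called (median -0.94, adjusted p = 0.00800, and adjusted p = 0.479 with an estimated correlation). Their median was -0.36 without SILP replicate 3, and the call was lost (adjusted p = 0.0839). Among 24 genes of immature and circulating monocytes the tested direction was down (median -0.74, or -0.64 with undetected genes at their bound, adjusted p = 0.0227, and adjusted p = 0.178 with an estimated correlation). That call was lost without SILP replicate 1 or 2 or blood replicate 2 (adjusted p = 0.139, 0.0598 and 0.0691). The list's only called member, the nuclear receptor gene Nr4a1, rose 8.56-fold. Nr4a1 lost its call when any array other than SILP replicate 3 was left out (adjusted p = 0.0574 to 0.110 in limma). Of 9 markers of Ly6Clo monocytes, the patrolling subset, Nr4a1 and Fabp4 rose (median 0.64, adjusted p = 0.00875, and adjusted p = 0.134 with an estimated correlation). Nr4a1 also stands in the immediate early list and Fabp4 in the cholesterol and lipid list, so neither call is particular to the Ly6Clo markers. The Ly6Clo median was 0.97 without blood replicate 3. When Ly6Chi, immature monocyte and Ly6Clo genes were each adjusted over the list alone, 0, 1 and 2 rose and 0, 1 and 1 fell, in that order. Itgam and Cx3cr1 were too dim to be tested, with their probes detected on 1 and 0 of the 6 arrays, and Ly6c2 and Il12b were not analysed here.

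Of 23 genes of macrophage maturation, 5 rose and none fell (median 0.91, adjusted p = 3.82e-07, and adjusted p = 0.178 with an estimated correlation). Among them were Cd14, the cholesterol exporter Abca1 (14.1-fold), the mannose receptor Mrc1 (6.82-fold, or 10.4-fold without SILP replicate 3) and the integrin Itgax (at least 3.53-fold). The remaining risen gene, Lyve1 (at least 2.73-fold), also stands in the list of stroma and endothelium. Mrc1 lost its call when any array other than SILP replicate 3 was left out (adjusted p = 0.0758 to 0.151 in limma). The maturation median against blood was 1.76 and 1.5 on SILP replicates 1 and 2 and -0.01 on SILP replicate 3, and over all arrays but 1 it was 0.51 without SILP replicate 1, 1.61 without SILP replicate 3 and 1.38 without blood replicate 3. Of 8 markers of resident intestinal macrophages, Mrc1 and Ccl8 rose (median 0.91, adjusted p = 0.00106, and adjusted p = 0.304 with an estimated correlation). Their median against blood was 1.79 and 1.58 on SILP replicates 1 and 2 and -0.30 on SILP replicate 3. The resident macrophage median was 0.47 without SILP replicate 1, 0.57 without SILP replicate 2, 1.65 without SILP replicate 3, 0.29 without blood replicate 2 and 1.43 without blood replicate 3. For 18 genes of MHC class II and antigen presentation the same medians were 0.16, 0.04 and -1.95. In that list H2-Oa, a modulator of peptide loading, fell by 1.18 on the log2 scale, and the list was not called (adjusted p = 0.623), while neutrophil markers stood 2.40 above blood on SILP replicate 3. H2-Oa lost its call when any array other than SILP replicate 3 was left out (adjusted p = 0.0711 to 0.227 in limma). None of 26 lysosomal genes was called (median 0.07, adjusted p = 0.0307, and adjusted p = 0.554 with an estimated correlation). The list's call was lost without SILP replicate 1 or 2 or blood replicate 1 (adjusted p = 0.256, 0.164 and 0.0635), and its median was -0.00128 without SILP replicate 1, -0.02 without SILP replicate 2 and 0.24 without SILP replicate 3. When maturation, resident macrophage, MHC class II and lysosomal genes were each adjusted over the list alone, 6, 2, 0 and 1 rose and 0, 0, 1 and 0 fell, in that order.

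In the cholesterol and lipid list the fatty acid binding proteins Fabp4 (20.9-fold) and Fabp5 (at least 7.78-fold) and Abca1 rose, 3 of 18, while the list's median was -0.02 and its mean 0.66 (tested direction up, adjusted p = 0.00875, and adjusted p = 0.156 with an estimated correlation). The lipid median was 0.06 without SILP replicate 1, -0.05 without SILP replicate 2, 0.11 without SILP replicate 3, 0.10 without blood replicate 1 and -0.01 without blood replicate 2. Slc7a11, a cystine importer (at least 11.7-fold, or 7.02-fold without SILP replicate 3, with 1 of its 4 probes called), and the metallothionein Mt2 (3.76-fold) rose among 25 genes of oxidative stress and metal handling (median 0.82, adjusted p = 2.91e-07, and adjusted p = 0.0633 with an estimated correlation). Of 17 genes of matrix remodelling, 3 rose, the protease genes Adam8 (17.3-fold) and Mmp13 (at least 1.99-fold) and the inhibitor Timp1 (at least 2.07-fold), at a median of 1.12, or 0.81 with undetected genes at their bound (adjusted p = 7.82e-06, and adjusted p = 0.0633 with an estimated correlation). The matrix median was 0.54 without SILP replicate 3. Against blood it was 0.58 and 0.53 on SILP replicates 1 and 2 and 1.33 on SILP replicate 3, where neutrophil markers stood 2.40 above blood. Of 25 genes of glycolysis and hypoxia, Vegfa, Hif1a, the hypoxia regulator, and Pfkfb3, an activator of glycolysis, rose (median 0.30, adjusted p = 1.62e-05, and adjusted p = 0.0671 with an estimated correlation). The glycolysis median was 0.18 without SILP replicate 1 and 0.18 without blood replicate 1. Of 20 trafficking and adhesion genes only Itgax was called (median 0.12, adjusted p = 0.0126, and adjusted p = 0.178 with an estimated correlation). The list's call was lost without SILP replicate 3 or blood replicate 2 (adjusted p = 0.171 and 0.0534), and its median was 0.35 without SILP replicate 1, -0.03 without SILP replicate 3, 0.06 without blood replicate 2 and 0.23 without blood replicate 3. When lipid, oxidative stress, matrix, glycolysis and adhesion genes were each adjusted over the list alone, 3, 7, 7, 3 and 3 rose and 0, 0, 1, 0 and 1 fell, in that order. Col3a1 and Sparc, which stromal cells make, were higher on the same arrays.

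The median over all 7976 genes was -0.18, and -0.43 with median scaling, so lists of growth and housekeeping genes are given relative to it. Medians of the other lists are given without this step. Relative to all genes, the prostaglandin median was 0.06 (-0.03 without SILP replicate 2) and the lipid median 0.16. The interferon-gamma median without SILP replicate 3 was then 0.06. No list's median relative to all genes changed sign under another scaling. None of 32 cell cycle genes was called (median -0.66 relative to all genes, adjusted p = 0.00875, and adjusted p = 0.554 with an estimated correlation). The list's call was lost without SILP replicate 3 or blood replicate 2 (adjusted p = 0.0976 and 0.424), and its median relative to all genes was -1.16 without blood replicate 1 and -0.02 without blood replicate 2. Against the mean of the blood arrays, its median was -0.90, 1.23 and -0.23 on blood replicates 1 to 3. None of 31 ribosomal protein genes was called (median -0.28 relative to all genes, adjusted p = 0.00209, and adjusted p = 0.554 with an estimated correlation), with the call lost without SILP replicate 3 (adjusted p = 0.0640). The ribosomal median relative to all genes was -0.08 without SILP replicate 3. None of 37 genes of oxidative phosphorylation was called (median -0.29 relative to all genes, adjusted p = 0.0215, and adjusted p = 0.677 with an estimated correlation). That list's median relative to all genes was -0.47 without SILP replicate 1, -0.47 without SILP replicate 2 and 0.03 without SILP replicate 3. Its call was lost without SILP replicate 3 (adjusted p = 0.876) and without blood replicate 3 (adjusted p = 0.0604). When cell cycle, ribosomal and oxidative phosphorylation genes were each adjusted over the list alone, 0, 0 and 0 rose and 0, 0 and 0 fell, in that order.

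Measured markers of several other cell types were higher in the SILP. Of members with a probe, 7 of 25 epithelial, 8 of 22 stromal, 8 of 14 T cell and 4 of 7 plasma cell genes were kept. Markers undetected in blood were kept only where every SILP array detected them, which favours high medians. The medians below cover the kept genes and not the whole lists. Jchain, the joining chain of secreted antibodies made by plasma cells, was at least 42.2-fold higher, and it was the only called gene of 4 plasma cell markers (median 2.12, or 1.61 with undetected genes at their bound). The plasma cell median was 1.54 without SILP replicate 1. Among 7 genes of the intestinal epithelium 3 rose (median 2.94, or 2.13 with undetected genes at their bound, adjusted p = 6.96e-10, and adjusted p = 0.128 with an estimated correlation), with the antimicrobial lectins Reg3b (at least 24.7-fold) and Reg3g (at least 5.85-fold). Among 8 genes of stroma and endothelium 4 rose (median 2.51, or 1.60 with undetected genes at their bound, adjusted p = 7.88e-07, and adjusted p = 0.0648 with an estimated correlation), with Col3a1, a fibrillar collagen (at least 14.2-fold, or 8.30-fold without SILP replicate 1), and Sparc (at least 16.8-fold). Among 8 T cell genes 3 rose (median 2.20, or 1.73 with undetected genes at their bound, adjusted p = 2.46e-06, and adjusted p = 0.138 with an estimated correlation), namely Ifng, Cd3g and Cd3e. Of 5 NK cell genes, Gzmb, granzyme B, rose at least 2.40-fold (median 0.29, adjusted p = 0.0215, and adjusted p = 0.178 with an estimated correlation), with the list's call lost without SILP replicate 1 or 3 (adjusted p = 0.0846 and 0.0839) and a median of 0.43 without SILP replicate 2 and 0.18 without SILP replicate 3. None of 6 dendritic cell genes was called (median 0.01, mean -0.02, adjusted p = 0.445). The dendritic cell median was -0.11 without SILP replicate 1, -0.09 without SILP replicate 2, 0.26 without SILP replicate 3, 0.14 without blood replicate 1, -0.29 without blood replicate 2 and 0.20 without blood replicate 3. The 8 neutrophil genes had a median against blood of -1.50 and -0.80 on SILP replicates 1 and 2 and 2.40 on SILP replicate 3, and the list was not called (median 0.62, adjusted p = 0.207). It was called as higher without SILP replicate 1 (adjusted p = 0.0118) and with median scaling (adjusted p = 0.0238), and its median was 1.25 without SILP replicate 1, -1.02 without SILP replicate 3 and 0.14 without blood replicate 1. S100a9, abundant in neutrophils and in immature monocytes, stood at 9.31, 10.31 and 13.57 (log2) on the SILP arrays and 11.33 ± 0.76 (SD, n = 3) in blood. When epithelial, stromal, T cell, NK cell, dendritic cell and neutrophil genes were each adjusted over the list alone, 6, 5, 6, 2, 0 and 0 rose and 0, 0, 1, 0, 0 and 0 fell, in that order. Platelet, B cell and Paneth cell markers had 2, 1 and 1 measured genes and no call, and erythroid, eosinophil and mast cell markers had 0 genes bright enough to test.

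**Figure D3:**
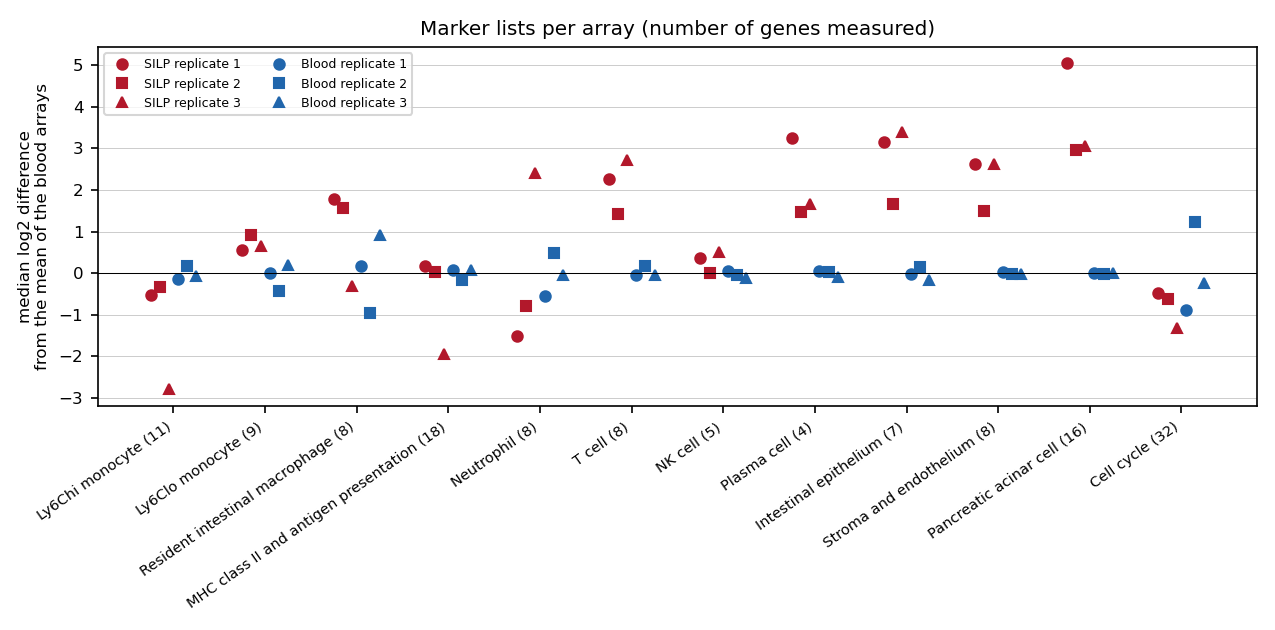
Median log2 difference of each marker list from the mean of the blood arrays (vertical axis) on each of the 3 SILP arrays (red) and 3 blood arrays (blue). Neutrophil markers stood at 2.40 and Ly6Chi monocyte markers at -2.79 on SILP replicate 3, and pancreatic acinar markers, a list added after the data were seen, at 5.05, 2.96 and 3.06 on the SILP arrays.

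**Figure D4:**
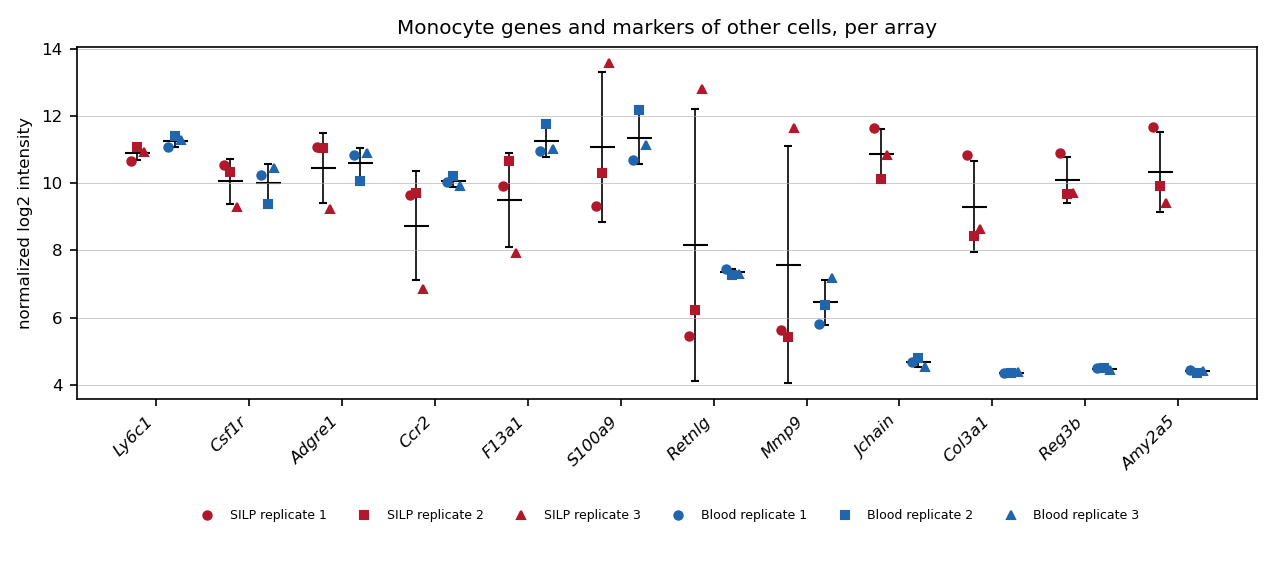
Normalized log2 intensity (vertical axis) of monocyte genes and of markers of other cells on the 3 SILP arrays (red) and the 3 blood arrays (blue), with bars for the mean and SD. Retnlg was 12.80 on SILP replicate 3 against 5.46 and 6.23 on the other SILP arrays, and Jchain, Col3a1, Reg3b and Amy2a5 were higher on every SILP array than on any blood array.

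Genes lower in the SILP included Grm5, a glutamate receptor gene (at least 4.08-fold, adjusted p = 0.00812), Ccdc171 (4.94-fold, adjusted p = 0.0148) and Tmpo, which encodes a protein of the nuclear lamina (4.52-fold, adjusted p = 0.00558, 2 of its 4 probes called). Lrrc29, Stn1, Dna2 and Bri3bp fell by 1.62 to 1.69 on the log2 scale. Ssbp2, Wdr38 and Galnt9, not detected on any SILP array, were at least 2.14-fold, at least 2.01-fold and at least 1.77-fold lower. Ccdc171, Lrrc29, Stn1, Dna2, Bri3bp, Ssbp2, Wdr38 and Galnt9 each lost their call when any single blood array was left out. All of these but Ccdc171 also lost it without SILP replicate 1 (adjusted p = 0.0561 to 0.159 in limma). Lrrc29, Dna2, Bri3bp and Ssbp2 lost it without SILP replicate 2 as well (adjusted p = 0.0520 to 0.128 in limma). Tmpo lost its call without blood replicate 1 (adjusted p = 0.0548). Grm5 lost its call without blood replicate 2 or 3 (adjusted p = 0.0533 and 0.0584). All of these genes were still called without SILP replicate 3. Rgs1, a regulator of G protein signalling (42.1-fold, or 66.5-fold without SILP replicate 3), Mmp10, a matrix protease (at least 16.8-fold), and Amy2a5, a pancreatic amylase (at least 29.0-fold, or 18.3-fold without SILP replicate 1), were among the 10 genes with the highest fitted differences in the other direction. Every called probe had its 3 SILP values on the same side of its 3 blood values.

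Leaving out SILP replicate 3 gave 674 probes higher and 497 lower (335 and 212 genes), including all 438 called with it, whereas leaving out blood replicate 1, 2 or 3 gave 124, 168 and 143 higher, 1, 3 and 4 lower, and 26, 34 and 29 of the 59 called genes named by rule. Among higher genes, Arg2, Col3a1, Cxcl3, Egr3, Gzmb, Hif1a, Mmp13, Mt2, Pfkfb3, Rel and Slc7a11 lost their call with any single blood array left out. Abca1, Arg1, Ccl8, Fosb, Il1rn, Itgax, Rsad2, Timp1, Ubd and Vegfa lost theirs without at least 1 blood array. Egr3, Gzmb, Hif1a, Mt2 and Vegfa also lost theirs without SILP replicate 1. Of the 32 lists, 27 passed the test with the preset correlation and 20 without SILP replicate 3. In camera with an estimated correlation 0 passed (lowest adjusted p = 0.0633, 11 lists at an unadjusted p under 0.05). Another split of the arrays, which mixed the tissues, gave 24 with the preset correlation.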

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

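The settings that left out SILP replicate 3 together with a second change, and the test of named probes only, were chosen after the result was seen. As reported, 376 probes were higher and 62 lower, all with a fitted difference of at least 2-fold, and 27 of 32 lists passed. Counts follow as higher and lower, with those of at least 2-fold by the fitted difference in brackets where these differ: 193 and 22 (192 and 16) with the authors' value table, 154 and 16 (147 and 8) with no background correction, 284 and 30 (282 and 26) with normexp on the probes' own signals, 270 and 26 with median scaling, 282 and 30 (281 and 30) with an offset of 50, and 153 and 17 with 1 probe per gene. They were 114 and 40 (105 and 26) with no filter on dim probes, 35 and 6 with detection on all 6 arrays, and 212 and 34 for probes with 1 symbol; these settings change which probes are tested. Array weights gave 1010 and 1072 (756 and 371), so 48.5% of calls were higher against 85.8% as reported; the weight of SILP replicate 3 was 0.0767. Cyclic loess (426 and 55), detection on at least 1 array (339 and 43) and the intensity trend (400 and 59) stayed within 1.5 times. Over settings without 1 array, higher probes ranged from 124 to 674 and lower ones from 1 to 497; those of at least 2-fold ranged from 124 to 605 and from 1 to 302; lists ranged from 20 to 26. The lowest counts came without blood replicate 1 (124 and 1) and the highest without SILP replicate 3 (674 and 497, and 605 and 302 of at least 2-fold). Leaving out blood replicate 2 or 3 gave 168 and 3, and 143 and 4, and leaving out SILP replicate 1 or 2 gave 281 and 19, and 386 and 31. With dim probes filtered again and SILP replicate 3 left out there were 753 and 489 (676 and 301). The labels do not state whether equal replicate numbers mark the same animals. Correlations of same-numbered deviations were -0.07, -0.08 and -0.11, which cannot decide it with 3 arrays per tissue. The replicate block gave 346 and 22. Of the 32 lists, 0 passed in limma's camera with an estimated correlation (11 at an unadjusted p under 0.05), 0 without SILP replicate 3 as well (8 unadjusted), and 14 passed with fry in both cases. With all 6 arrays required to detect a probe, 18 of the 27 lists that could still be tested passed, and the signed -log10 adjusted p of the Ly6Clo monocyte list turned to -0.0274. That of the oxidative phosphorylation list turned to 0.0575 without SILP replicate 3, to 0.000339 with dim probes filtered again and to 0.0248 with an estimated correlation as well. Retnlg, a neutrophil gene, turned from 0.82 to -1.54 (log2) without SILP replicate 3, filtered again or not, and was called there. Other values turned that were called in neither setting. Without SILP replicate 3, filtered again or not, Mmp9 turned from 1.12 to -0.95, Adgre1 from -0.14 to 0.45 and Gp9 from 0.22 to -0.17. With array weights these 3 and Retnlg turned to -0.93, 0.28, -0.35 and -1.49. Median scaling turned Csf1r (-0.24), Ptges (-0.0754) and Gp9 (-0.0867), the authors' value table Csf1r (-0.0163) and cyclic loess S100a9 (0.0935). The MHC class II, unfolded protein response and neutrophil lists (-0.205, -0.0287 and 0.683 as reported) turned to 1.02, 1.01 and -1.11 without SILP replicate 3 and 0.931, 0.897 and -1.16 with dim probes filtered again. They turned to 0.259, 0.282 and -0.352 without it and with an estimated correlation, 0.355, 0.429 and -0.765 without it in fry, and 0.692, 0.985 and -0.841 with array weights. The unfolded protein response list also turned with detection on all 6 arrays (0.0717) and with the mean over a gene's probes (0.0198). Ranges without 1 array, for results that turned there, were -1.54 to 2.20 for Retnlg, -0.95 to 2.20 for Mmp9, -0.46 to 0.45 for Adgre1, -0.17 to 0.57 for Gp9, -0.28 to 0.41 for Csf1r, -1.08 to 0.22 for S100a8 and -1.48 to 0.61 for S100a9. They were -2.71 to 0.0575 for the oxidative phosphorylation list, -0.825 to 1.02 for MHC class II, -0.379 to 1.01 for the unfolded protein response and -1.11 to 1.93 for neutrophils. The cause of these changes was not tested. In all, 25 and 23 values of single genes and of lists turned, 254 and 111 kept their direction and lost their call, 33 and 3 kept it and gained one, and 1523 and 626 kept direction and call. A slide block was not run, since no slide was named. The dimmer signal of SILP replicate 3 limits what that array can show.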

Other observations

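All tests in this part were chosen after the result was seen. Transcripts of pancreatic acinar cells, which make digestive enzymes, were found on every SILP array, in a list written after Amy2a5 appeared among the highest fitted differences. Of 27 such genes with a probe, 16 were kept by the filter. Of these 16, 10 rose and 6 did not pass the test (median 3.75, or 2.74 with undetected genes at their bound, and 3.02 without SILP replicate 1). They included Amy2a5 (at least 29.0-fold, or 18.3-fold without SILP replicate 1), the regenerating-family gene Reg2 (at least 13.2-fold) and Ctrb1, a chymotrypsinogen (at least 10.1-fold, or 6.57-fold without SILP replicate 1). Amy2a5 stood at 11.68, 9.91 and 9.40 (log2) on the SILP arrays. Zg16 and Reg1 in this list are also made in the gut epithelium.

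Genes outside the fixed lists, chosen after their values were seen, rose as well. Ctla4, an inhibitory receptor of T cells, was 25.2-fold higher, Il7r, the interleukin-7 receptor, 8.98-fold and Il21, a T cell cytokine, at least 1.59-fold. Ccrl2, an atypical chemokine receptor, was 24.7-fold higher, and Igfbp5, a growth factor binding protein of stroma, at least 10.7-fold. Of the 376 probes called higher, 142 had no gene symbol, as had 33 of the 50 with the highest fitted differences.

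The first pattern is the higher medians of the inflammatory cytokine, chemokine, regulatory and NF-kB lists in the SILP, with 82 measured genes. Of their 17, 18, 24 and 25 measured members, 7, 11, 8 and 3 were called. In camera with an estimated correlation none of these lists passed (adjusted p = 0.0633, 0.0633, 0.0648 and 0.178). Against neutrophils in SILP replicate 3 as the whole cause, the median over all 82 without that array was 1.21, or 1.15 with undetected genes at their bound. The neutrophil list was then at -1.02 against blood. In 10000 random lists of as many measured genes the median was at most 0.11. The lists were pooled with their values known, and random lists ignore correlation between genes, so that comparison measures no certainty. Against RNA or cells of epithelium, stroma, pancreas or plasma cells together as the whole cause, SILP replicate 1 minus replicate 2 was compared. Its median was -0.0720 over the 82 genes (quartiles -0.26 to 0.29). Over 35 markers of those tissues it was 1.66 (1.22 to 2.09), which rests on those SILP arrays alone. Of the 35 markers, 16 were pancreatic. Medians of the single lists were 1.90 for pancreas, 1.23 for plasma cells, 1.24 for epithelium and 0.91 for stroma. The pooled quartiles therefore do not stand for each source alone. The comparison covers the 82 genes as a set, most of them not called, and cannot decide the source of single called members. Among called chemokines, Cxcl12 and Cxcl13 leaned to SILP replicate 1, as those markers did, and Ccl2 and Ccl24 to replicate 2. Isolation from tissue and a response of monocytes to the gut cannot be told apart, because every SILP array came from tissue and no blood array did (immediate early list 1.65). RNA of T cells, macrophages or other immune cells stays open, as does a biological difference between the tissues. The sort should leave out most of these other cells but not free RNA, and the gate's other markers were not given in the sources used here. The real split called 438 probes (2149 at an unadjusted p under 0.05 in limma) and 27 lists. Other splits called at most 0 probes (502 at an unadjusted p under 0.05 in limma) and 24 lists. Each other split mixes the tissues, so a tissue difference widens the spread within its groups and in part remains between them. Its counts are therefore no measure of chance. Of the 10 splits, 1 reached each real value, too few splits for a share under 0.05.

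SILP replicate 3 stood apart, with 322 probes at least 4-fold above and 616 below both other SILP arrays, against 21 and 0 for replicate 1 and 0 and 18 for replicate 2. A dimmer array as the whole cause is argued against by 24 of all 25 neutrophil-list probes, detected or not, that were brighter on it before normalization than on both other SILP arrays, against 2.56% of all probes and 8.35% of those detected on it. Neutrophils among its sorted cells are a candidate explanation: the neutrophil list was 3.10 above the other SILP arrays and the Ly6Chi monocyte list -1.61, though the bounds of that test were set with the values known. On that array S100a9, S100a8 and Retnlg stood at 13.57, 13.28 and 12.80 (log2), and 5 of the list's 8 genes, S100a8, S100a9, Lcn2, Mmp8 and Mmp9, also stand in other lists. A sort on high Ly6C should leave out most neutrophils, the gate's other markers were not given in the sources used here, and a biological difference between pools stays untested.

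Pooled, the called markers of the pancreatic, plasma cell, epithelial and stromal lists were higher on SILP replicate 1 than on replicate 2. Over these 18 genes the median excess was 1.62. In 10000 random lists of as many other called-higher genes it was at most 1.56, so 0% were as high. Of the called markers, 10 were pancreatic, 1 plasma cell, 3 epithelial and 4 stromal. Over all measured members the excess was 1.90, 1.23, 1.24 and 0.91, in that order. The other called-higher genes had quartiles of -0.02 to 1.29, so the pooled excess does not show an excess in each list. Random lists also ignore correlation between genes. On SILP replicate 3 the lists parted: epithelial and stromal medians against blood (3.39 and 2.63) lay near those of replicate 1 (3.15 and 2.62), and pancreatic and plasma cell medians (3.06 and 1.66) near those of replicate 2 (2.96 and 1.47). RNA or cells carried over from the surrounding tissue, in a make-up that varied between arrays, may be a source, as a hypothesis found and tested on the same data, since the pancreatic list was written after Amy2a5 was seen. The sort should remove such cells but not free RNA, and transcription of these genes by the monocytes themselves was not tested.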
